A study of Mus musculus with 8 samples.

How the data were processed

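RNA of sorted bone marrow progenitors was measured on 8 one-colour Affymetrix arrays. The cells came from lineage-depleted marrow of Id2-GFP reporter mice, in which a green fluorescent protein reports activity of the Id2 gene, and were lysed straight after sorting, per the labels' protocols. The RNA was extracted with magnetic beads, amplified with a whole transcriptome kit and labelled with biotin, per the labels' protocols. Such amplification can add spread between arrays that does not come from the cells.

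The deposited values are log2 expression values per probe set, made by the authors with RMA and Partek, per the submitters' processing notes. RMA corrects the background, equalizes the distributions of probe signals between arrays and combines the probes of a probe set. The settings and versions of these steps are not given in the sources used here, and scanner files were not used here. The log2 scale was taken from the values, whose array medians lie between 3.93 and 4.26. The distributions of the deposited values are not identical, with SDs over all probe sets from 1.39 to 1.88. The deposited values carry no detection calls, so a gene below an array's median over all probe sets is taken as near background there. Where a dimmer group held such values, they were set to that median for the fold, which is then written as at least that many fold, while log2 differences and their errors are as fitted. This floor was chosen after seeing the data. Array values carry no read depth, so the number of arrays limits the precision.

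The table held 45141 probe sets. Gene names came from the platform annotation, with symbols compared with RefSeq through the Entrez gene number. That annotation gave 1 gene symbol to 28898 probe sets and several symbols to 551, and 15692 probe sets were not listed with a gene. No gene was named from a probe set with several symbols. Of the probe sets with 1 symbol, 28689 matched RefSeq and 0 symbols changed. They covered 17097 genes, of which 7180 had more than 1 probe set. A gene was represented by its probe set with the highest mean over the 8 arrays. It was tested if that value was above the array's median over all probe sets on at least 2 of the 8 arrays, which left 11583 genes. Some genes of the fixed lists, among them Tox, Il7r, Tcf7 and Lck, had no probe set with a single symbol and were not analysed here.

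The samples formed 4 groups of 2 from the labels, by genotype (wild type, WT, or Nfil3 knockout, KO) and by population (ALP, all-lymphoid progenitors, or preproNK, prepro NK cells). The labels do not say how many mice gave each sample. The p-values measure only the spread between these samples, which may be partly technical. One linear model with a mean for each of the 4 groups was fitted to all 8 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), which leaves 4 residual degrees of freedom. All tests were two-sided. P-values were adjusted by the method of Benjamini and Hochberg over the genes tested in a comparison, and a gene was called at an adjusted p under 0.05. There were 7 comparisons: KO against WT in each population, preproNK against ALP in each genotype, the interaction, and the means of both pairs of effects.

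The gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the 17 lists in a comparison. Lists needed at least 5 tested members. Camera with a correlation estimated per list and fry, a rotation test of whether a list's genes move on balance one way, were alternatives. A list of sex-linked genes served only to check the arrays. The fitted design, the lists, the rule for named genes and, except where said, the alternatives were set before the data were examined.

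The genes named in the text were chosen by that rule. It takes Nfil3 in every group, the called genes with the largest rises and falls that had the same sign in both replicates (up to 10 each way), and per list up to 4 called members. Of a list with no call it takes up to 2 members with the smallest unadjusted p, and where a comparison had fewer than 5 calls in a direction, the 5 genes with the smallest unadjusted p in that direction. Values of Id2, Eomes, Tbx21, Ets1, Gata3, Zbtb16, Il2rb, Flt3 and Rag1 are always given. The selection was shortened from the end, as the rule allows, and genes outside it are marked as chosen after their values were seen. Probes of paralog families (Klra, Klrc, H2, Gzm, Vpreb) can share targets.

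Replicate number marks the processing date in the series design, so the numbers pair the samples. Sex-linked genes also went with the number on all arrays but WT preproNK replicate 2, so the block does not separate date from that difference. The deviations of the replicate 1 arrays from their group means correlated across genes in every pair of groups. The r was 0.608 to 0.807 among WT ALP, KO ALP and WT preproNK, and 0.149 to 0.205 in pairs with KO preproNK. In WT ALP, KO ALP and WT preproNK the replicate 2 array had the lower SD over all probe sets. In KO preproNK the SDs were close (1.825 and 1.816). The high r therefore cannot separate date from the range of values. The blocked fit adds the replicate number as a term and has 3 residual degrees of freedom. The deposited values were not adjusted for date, since the median absolute difference between the 2 dates over genes was 0.47 log2.

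Alternatives were the blocked fit, leaving out each array in turn, no filter or a filter at the 75th percentile, the mean of a gene's probe sets, each probe set on its own, repeated quantile normalization, centring each array on its median, a trended and robust variance prior, only the 4 arrays of a comparison, and each replicate number alone. Array weights, and the blocked fit without the WT preproNK replicate 2 array, were added after seeing the data, as were percentiles of list medians among lists matched on mean level. The matched lists were drawn gene by gene, so these percentiles do not allow for correlation between the genes of a list. Extreme percentiles are therefore easier to reach for genes that move together. The first estimate of the array weights stopped before reaching its tolerance, so limma's gene by gene estimate was also run.

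The scripts were tested on simulated data with the real gene means and spreads. The noise was independent between genes, with no array that stood apart and no date effect, so the shares recovered need not hold for the real arrays. For KO against WT in preproNK, over 11583 genes, the fit recovered 2% of genes changed by 1 log2 unit, 30% of those changed by 2, 98% of those changed by 4 and 100% of those changed by 6, and called 5 unchanged genes. For the population difference averaged over both genotypes these shares were 4%, 74%, 100% and 100%, also with 5 unchanged genes called. A T lineage list shifted by 1 log2 unit had a camera adjusted p of 2.23e-13 and 0 other lists were called. With independent genes this cannot show how often camera calls lists whose genes move together.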

Results

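Gene expression was profiled in 2 bone marrow progenitor populations of mice with and without Nfil3, a bZIP transcription factor needed for the development of natural killer (NK) cells. The all-lymphoid progenitor (ALP) is an early progenitor of the lymphoid lineages, and the prepro NK cell (preproNK) is a later progenitor on the way to NK cells. The series title names a differential requirement for Nfil3 along NK cell development as its subject. Each of the 4 groups (WT ALP, KO ALP, WT preproNK and KO preproNK) had 2 arrays, 1 for each of 2 processing dates. Replicate 1 and replicate 2 denote those dates.

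The WT preproNK replicate 2 array stood apart from the other 7. Its correlations across tested genes with the other arrays were highest with WT ALP replicate 2 (0.747) and KO ALP replicate 2 (0.656), against 0.621 with the other array of its group, 0.599 and 0.574 with the KO preproNK arrays and 0.55 and 0.504 with the remaining ALP arrays. The KO preproNK arrays correlated with each other at 0.963. Its values had an SD of 1.39 log2 over all probe sets, against 1.55 to 1.88 on the others. Only 310 of the tested genes reached a log2 value of 8 on it, against 682 to 1498 on the other arrays. The WT ALP replicate 2 array had the next lowest SD (1.55) and the next lowest number of such genes (682). Both WT groups therefore had 1 array with a narrow range of values.

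Nfil3 (Entrez gene 18030, 1 probe set) was lower in the KO arrays of both populations. In ALP its log2 value was 6.19 ± 0.98 in WT and 3.78 ± 0.52 in KO (SD, n = 2 each). In preproNK it was 4.74 ± 0.01 in WT and 3.71 ± 0.19 in KO (SD, n = 2 each). The log2 difference between KO and WT was -2.41 (SE 0.52) in ALP and -1.04 (SE 0.52) in preproNK, and neither was called by limma (adjusted p = 1 and 0.613). All 4 KO arrays lay below all 4 WT arrays. Whether the probe set lies in the deleted part of the gene is not known, so these values are not a full check of the labels.

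**Figure D1:**
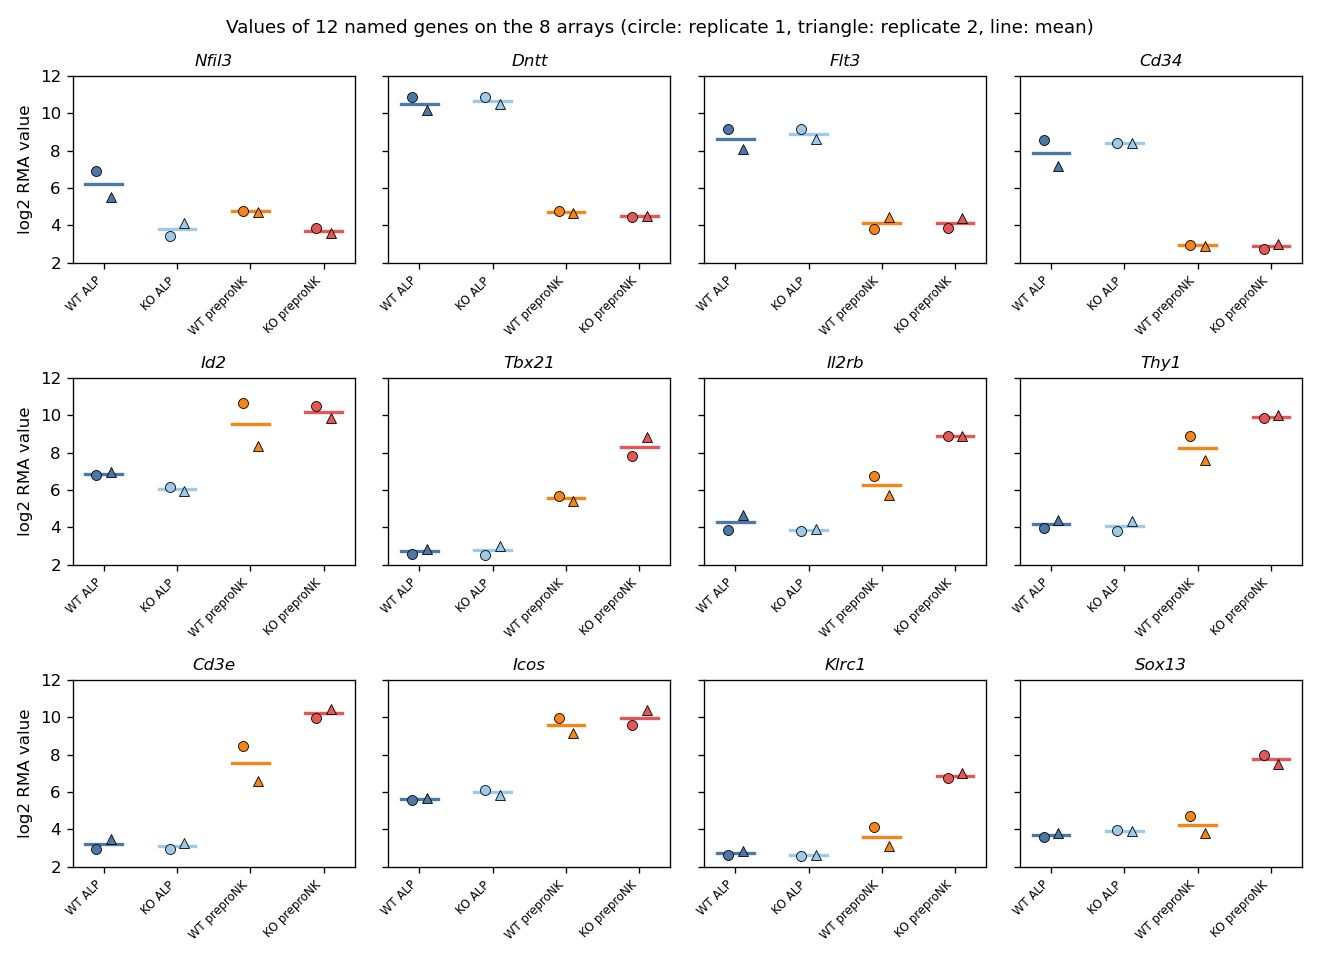
Log2 RMA values (vertical axes) of 12 named genes in the 4 groups (horizontal axes), with circles for replicate 1, triangles for replicate 2 and lines for the mean of the 2 arrays. Dntt, Flt3 and Cd34 were lower in preproNK than in ALP in both genotypes, and the KO preproNK arrays had the highest values of Tbx21, Il2rb, Cd3e, Klrc1 and Sox13.

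The levels of the transcription factors and receptors followed throughout were as follows. The log2 value of Id2, an inhibitor of E proteins and the gene behind the reporter, was 6.88 ± 0.08 in WT ALP, 6.05 ± 0.15 in KO ALP, 9.53 ± 1.64 in WT preproNK and 10.17 ± 0.44 in KO preproNK (SD, n = 2 each). Tbx21, which encodes T-bet, was at 2.71 ± 0.21, 2.78 ± 0.33, 5.55 ± 0.18 and 8.33 ± 0.69 in the same order of groups. Il2rb, the receptor chain shared by interleukins 2 and 15, was at 4.27 ± 0.57, 3.84 ± 0.09, 6.26 ± 0.72 and 8.90 ± 0.01. Zbtb16, which encodes PLZF, was at 3.999 ± 0.32, 4.05 ± 0.28, 6.15 ± 0.28 and 7.02 ± 0.38. Gata3 was at 3.28 ± 0.11, 3.31 ± 0.38, 6.13 ± 2.35 and 5.97 ± 0.43, and the SD in WT preproNK came from values of 7.79 and 4.46 on its 2 arrays. Ets1 was at 6.17 ± 1.07, 6.76 ± 0.56, 7.92 ± 2.06 and 9.21 ± 0.03. Eomes was at 4.17 ± 0.34, 3.97 ± 0.27, 4.88 ± 1.19 and 4.42 ± 0.05, with 4.04 and 5.73 on the WT preproNK arrays. Flt3, a cytokine receptor of early progenitors, was at 8.62 ± 0.73, 8.89 ± 0.35, 4.13 ± 0.48 and 4.11 ± 0.38. Rag1, part of the recombinase of antigen receptor genes, was at 3.85 ± 0.22, 4.14 ± 0.22, 3.82 ± 0.80 and 3.18 ± 0.34.

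In preproNK, the question was what loss of Nfil3 does in cells already past the early progenitor. No gene passed the test over all genes in the fit without the replicate number as a block, and the 5 genes with the smallest unadjusted p all had higher values in KO. Sox13, a transcription factor of gamma delta T cells, had a log2 difference of 3.48 (SE 0.42). Cd55, a complement inhibitor, differed by 3.43 (SE 0.39), Klrc1, which encodes an NKG2 receptor, by 3.26 (SE 0.42), S1pr1, a receptor for exit from tissues, by 2.76 (SE 0.36) and Sit1, an adaptor of T cell receptor signalling, by 2.74 (SE 0.36). Each of these 5 had an adjusted p of 0.16, one of 0.0457 with the block, and the same sign in both replicate pairs. On WT preproNK arrays Cd55 (mean 2.70) was below the median of both and Klrc1 and Sox13 were below that of 1, so their differences are set against values near background, and with that floor they were at least 3.95-fold, 6.46-fold and 9.52-fold higher. The 5 genes with the smallest unadjusted p in the other direction had lower values in KO. They were Lrrc52 (-2.27, SE 0.35), Pparg, a nuclear receptor (-2.36, SE 0.50), Asph (-1.99, SE 0.46), Gm15527 (-1.88, SE 0.40) and Tmem273 (-1.79, SE 0.41), with adjusted p from 0.185 to 0.427, and Lrrc52, Asph and Gm15527 were below the array medians on both KO preproNK arrays. Other probe sets of some of these genes differed far less. Those of Cd55 differed by 0.19 (mean level 3.39 against 3.41) and 0.43, and that of Klrc1 by 0.25. Those of Lrrc52 and Tmem273 differed by -0.33 and -0.10, and those of Asph by -0.98 to 0.07. Sox13, S1pr1, Sit1, Pparg and Gm15527 had no other probe set.

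The T lineage list moved up as a group in KO preproNK by camera (adjusted p = 1.03e-09), with a median log2 difference of 1.69. The adjusted p was 0.176 with an estimated correlation and 0.0243 by fry. Of its 15 tested members 0 were called over all genes and 11 were higher when adjusted over the list alone, and Cd28, a costimulatory receptor, had a log2 difference of 2.62 (SE 0.38). The list's median was 1.56 in the replicate 1 pair and 1.93 in the replicate 2 pair. Over all tested genes, the difference between KO and WT preproNK in the replicate 2 pair, which holds the narrow-range array, went with the level of the gene. Its median there was -0.555 over the 2896 genes dimmest in ALP and 1.4 over the 2896 brightest, against -0.0259 and 0.0431 in the replicate 1 pair and -0.31 and 0.745 in the mean of both. Cytotoxic effectors and chemokines (adjusted p = 0.000674, 0.176 with an estimated correlation) had 6 of 14 members higher when adjusted over the list alone, and the chemokine gene Ccl5 differed by 2.12 (SE 0.42). The interleukin receptor list (adjusted p = 0.00058, 0.458 with an estimated correlation) had 3 of 14, with Il2rb at a difference of 2.64 (SE 0.46). NK receptors (adjusted p = 0.0027, 0.294 with an estimated correlation) had 4 of 15 higher when adjusted over the list alone. The cell cycle list was also called (adjusted p = 9.84e-06, 0.458 with an estimated correlation) with 0 of 28 members past either gene test. Its member Aurkb, a mitotic kinase, had a difference of 2.76 (SE 0.77), from 1.08 in the replicate 1 pair and 4.43 in the replicate 2 pair. The erythroid list had lower values (adjusted p = 0.0036, 0.241 with an estimated correlation) with 0 of 12 members past either gene test, and Slc4a1 differed by -0.75 (SE 0.40). In the replicate 1 and replicate 2 pairs the medians were 1.15 and 1.62 for the cytotoxic list, 0.577 and 1.88 for interleukin receptors, 0.123 and 1.00 for NK receptors, 0.346 and 1.58 for cell cycle genes and -0.52 and -0.406 for erythroid genes. Among 10000 lists matched on mean level these lay at percentiles 100 and 99.88, 100 and 99.84, 91.53 and 99.46, 99.97 and 97.18, and 0 and 37.6, and the T lineage medians at 100 and 99.99. Markers of dendritic cells, a list not called here, had a median of -0.434 in the replicate 1 pair and 1.32 in the replicate 2 pair. The mast cell and megakaryocyte list, with a median of -0.40, was not called (adjusted p = 0.0533) but was with the replicate number as a block (adjusted p = 0.0461). Without WT preproNK replicate 1 the NK receptor, cytotoxic and erythroid lists lost their call (adjusted p = 0.064, 0.0778 and 0.064), as did the erythroid list without KO preproNK replicate 1 (adjusted p = 0.0953). Without the narrow-range array 9 lists were called, the 6 above and, all down, innate lymphoid precursor (adjusted p = 0.0137), early lymphoid progenitor (0.00452) and clock genes (0.0106). The innate lymphoid precursor list had not been called, upward, with all arrays (adjusted p = 0.239), and was called upward without WT preproNK replicate 1 (0.0238). The dendritic cell list was called up without KO preproNK replicate 1 (adjusted p = 0.00342) and down without KO preproNK replicate 2 (0.0102). Without the first of these 2 arrays interferon response genes (adjusted p = 0.0366) were also called up and mast cell (0.00272) and clock genes (0.0126) down, and without the second early lymphoid progenitor genes down (0.0421).

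**Figure D2:**
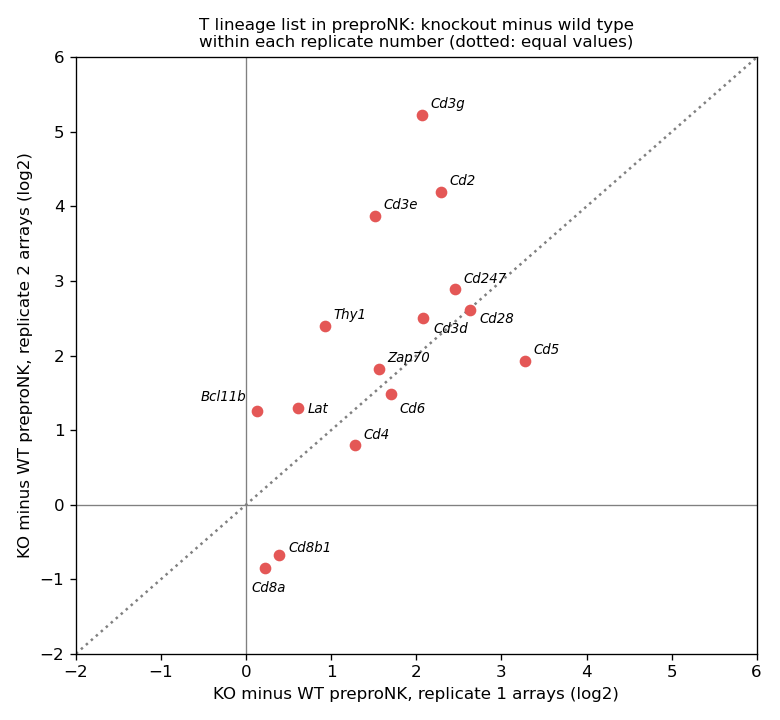
Log2 difference between KO and WT preproNK for each of the 15 tested members of the T lineage list, in the replicate 1 arrays (horizontal axis) and in the replicate 2 arrays (vertical axis), with 1 array against 1 in each. For 13 members the difference was above 0 on both axes, and Cd8a and Cd8b1 were below 0 in the replicate 2 pair.

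Of the genes always followed, Tbx21 had a log2 difference of 2.78 between KO and WT preproNK (SE 0.44, adjusted p = 0.188) and Zbtb16 one of 0.87 (SE 0.40, adjusted p = 0.613). The other probe set of Zbtb16, with a mean level of 5.08 against 5.31, differed by 2.31. Differences of Ets1 (1.30, SE 0.91), Id2 (0.65, SE 0.69), Flt3 (-0.02, SE 0.49), Gata3 (-0.16, SE 0.93), Eomes (-0.46, SE 0.56) and Rag1 (-0.64, SE 0.46) were within 2 standard errors of 0. By limma, 0 of 11583 genes were called in this comparison and 625 had an unadjusted p under 0.05, 522 of them with higher values in KO. The median difference over all tested genes was 0.15 log2. With the replicate number as a block, 10 genes were called, all higher in KO (Actn2, Cd247, Cd55, Cst7, Ehd3, Klrc1, S100a6, S1pr1, Sit1 and Sox13, each with an adjusted p of 0.0457; Actn2, Ehd3 and S100a6 are named here after their values were seen), and adding the removal of the WT preproNK replicate 2 array gave 47, with 27 higher and 20 lower. Without the WT preproNK replicate 1 array, which leaves the narrow-range array as the only WT preproNK sample, 2532 genes were called, and without the narrow-range array alone 0 were.

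In ALP, the question was what loss of Nfil3 does in the earlier progenitor. Nfil3 itself had the largest difference among the genes named by the rule, and no gene was called. The 5 genes with the smallest unadjusted p among those with higher values in KO were Auh (1.36, SE 0.44), Scpep1 (1.11, SE 0.45), Mid1 (1.08, SE 0.44), Sox12 (0.82, SE 0.35) and Pradc1 (1.32, SE 0.61). Those with lower values were Nfil3 itself, Iftap (-0.84, SE 0.36), Pnliprp2 (-1.004, SE 0.44), Tenm2 (-0.84, SE 0.38) and Nectin1 (-0.96, SE 0.46). All 10 had an adjusted p of 1. Of the NK regulators, Id2 differed by -0.83 (SE 0.69) and Il2rb by -0.43 (SE 0.46), both with an adjusted p of 1.

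By camera the cell cycle list moved up in KO ALP (adjusted p = 0.0087, 0.783 with an estimated correlation) with 0 of 28 members past either gene test, and its member Mcm6, a replication helicase subunit, differed by 1.24 (SE 0.88). The T lineage list moved down (adjusted p = 0.0325, 0.783 with an estimated correlation) with 0 of 15 members past either gene test, a median of -0.11 and Cd3d at -0.63 (SE 0.52). The knockout effect in ALP went with the level of the gene, with a median of -0.138 over the 2896 genes dimmest in ALP and 0.255 over the 2896 brightest. Among 10000 lists matched on mean level, an alternative chosen after seeing the data, the cell cycle median of 0.38 lay at percentile 99.32 (91.12 and 98.16 in the replicate 1 and replicate 2 pairs) and the T lineage median at 1.13 (0.03 and 2.88). With the replicate number as a block the adjusted p of both lists was 0.0532. The cell cycle list had an adjusted p of 0.645 with the direction turned without the narrow-range WT ALP replicate 2 array and one of 0.55 without KO ALP replicate 1, and leaving out any 1 ALP array gave the T lineage list one of 0.0615 to 0.55. After repeated quantile normalization neither was called (adjusted p = 0.136 and 0.133), and without a filter on dim probe sets the T lineage list was not (0.447). Early lymphoid progenitor genes were called up without WT ALP replicate 1 (adjusted p = 0.0353) and immediate early genes up without KO ALP replicate 1 (0.0428). By limma 0 genes were called in ALP, with and without the block, and 5 of 11583 had an unadjusted p under 0.05. A well calibrated test would put a share near 0.05 of the genes there even if no gene differed. The count of 5 is far below that share, so it is no evidence that loss of Nfil3 changes nothing in ALP. The fit shares 1 estimate of the spread over the 4 groups, among them WT preproNK with the array that stood apart. The cause of the low count was not tested.

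The interaction asked whether the knockout effect on RNA levels differed between the populations. It bears on the differential requirement in the title only through the RNA of the sorted cells. It does not test whether cells need Nfil3 to form or progress. The genes with the smallest unadjusted p and a more positive knockout effect in preproNK included the NK receptor gene Klrc1 and the T cell adaptor gene Sit1, but no gene was called by limma. Cd55 had an interaction of 3.52 (SE 0.56), the scavenger receptor gene 5830411N06Rik one of 3.44 (SE 0.60), Klrc1 3.39 (SE 0.59), Ehd3 2.99 (SE 0.55) and Sit1 2.82 (SE 0.51). In the other direction stood Asph (-2.59, SE 0.65), Lrrc52 (-2.31, SE 0.49), Pparg (-2.27, SE 0.71), Ccdc184 (-1.83, SE 0.64) and Gm15527 (-1.76, SE 0.57). The adjusted p of each was 1. The interaction of Nfil3 itself was 1.37 (SE 0.73). Cd55, Klrc1, Asph and Lrrc52 were near background in preproNK on 1 or both arrays of the dimmer genotype. With the floor their differences there were 1.98 in place of 3.43, 2.69 in place of 3.26, -1.38 in place of -1.99 and -1.25 in place of -2.27. No interaction was fitted with the floor. The other probe sets of these 4 genes differed less in preproNK, as given above.

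By camera 8 of 17 lists were called for the interaction, 6 up and 2 down, and 0 of them with an estimated correlation or by fry. The median knockout effect over the genes dimmest and brightest in ALP was -0.138 and 0.255 in ALP, and -0.31 and 0.745 in preproNK. The interaction can carry this trend with level, and its list calls were not matched on level. The T lineage list had the smallest adjusted p (5.81e-20, 0.0812 with an estimated correlation) with 7 of 15 members higher when adjusted over the list alone and Cd28 at 2.33 (SE 0.53). The interleukin receptor list (adjusted p = 9.81e-06, 0.405 with an estimated correlation) included Il2rb at 3.06 (SE 0.66), and the NK transcription factor list (adjusted p = 0.00417, 0.405 with an estimated correlation) included Tbx21 at 2.71 (SE 0.62). NK receptors had an adjusted p of 9.81e-06 (0.137 with an estimated correlation) and cytotoxic effectors, with Ccl5 at 2.13 (SE 0.60), one of 4.89e-05 (0.0812 with an estimated correlation). The cell cycle list had an adjusted p of 0.000648 (0.553 with an estimated correlation) and Aurkb a value of 2.08 (SE 1.09). Early lymphoid progenitor genes, with Rag2 at -1.56 (SE 0.61), had an adjusted p of 0.000938 (0.309 with an estimated correlation), and erythroid genes, with Alas2 at -0.72 (SE 0.51), one of 0.0136 (0.288 with an estimated correlation). By limma 0 of 11583 genes were called with or without the block, and 183 had an unadjusted p under 0.05. That count too lies below a share of 0.05, so the 0 calls are no evidence of equal effects. Without the WT preproNK replicate 2 array 6 lists were called, and the NK transcription factor and erythroid lists were no longer among them (adjusted p = 0.298 and 0.164). Leaving out another array ended the call of NK transcription factors once (adjusted p = 0.117 without KO ALP replicate 1), of cytotoxic effectors once (0.0636 without WT preproNK replicate 1), of early lymphoid progenitor genes without WT ALP replicate 2 or WT preproNK replicate 1 (0.254 and 0.128), of cell cycle genes without WT ALP replicate 1, WT preproNK replicate 1 or KO preproNK replicate 2 (0.295, 0.0706 and 0.789), and of erythroid genes without WT ALP replicate 1, WT preproNK replicate 1 or KO preproNK replicate 1 (0.0955, 0.0908 and 0.322). The innate lymphoid precursor list, not called upward with all arrays (adjusted p = 0.0712), was called without KO ALP replicate 2, KO preproNK replicate 2, WT ALP replicate 1 or WT preproNK replicate 1 (0.00941, 0.0195, 0.0242 and 0.00394). Without KO preproNK replicate 1 the dendritic cell list, at an adjusted p of 0.529 with all arrays, was called up (3.01e-05), as were interferon response genes (0.0148), with clock (0.048) and mast cell genes (0.00585) down, and mast cell genes were also called without KO ALP replicate 1 (0.0336).

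Averaged over both populations, the knockout had 0 called genes by limma, with and without the block, and 352 genes had an unadjusted p under 0.05. The count of 352 is also below a share of 0.05 of the genes tested. The genes with the smallest unadjusted p were higher in KO for Sox13 (1.87, SE 0.30), Cd55 (1.67, SE 0.28), Actn2 (1.54, SE 0.27), S1pr1 (1.42, SE 0.25) and Cd28 (1.45, SE 0.27). They were lower in KO for Nfil3 (-1.72, SE 0.37), Lrrc52 (-1.12, SE 0.25), Gm15527 (-0.996, SE 0.28), Ugt3a2 (-2.004, SE 0.58) and Pparg (-1.22, SE 0.35), and the adjusted p of each of the 10 was 0.638. Cd55, Lrrc52, Gm15527 and Ugt3a2 were below the array medians on all 4 arrays of the lower genotype, and with those levels set to the medians their differences were 0.15, -0.12, -0.70 and -1.40. Sox13 and Nfil3 were below on 3 of those 4 arrays (1.57 and -1.45 with the floor) and S1pr1 and Cd28 on 2 (1.19 and 1.21). Tbx21 stood at 1.42 (SE 0.31), or 0.76 with the floor. Of the 17 lists camera called 5, and 0 with an estimated correlation. They were the T lineage (adjusted p = 3.9e-05, 0.342 with an estimated correlation), cell cycle (adjusted p = 1.3e-05, 0.523 with an estimated correlation), cytotoxic (adjusted p = 0.00769, 0.342 with an estimated correlation) and interleukin receptor lists (adjusted p = 0.00782, 0.583 with an estimated correlation), all up, and the erythroid list, down (adjusted p = 0.00782, 0.342 with an estimated correlation). Their members with the smallest unadjusted p included Aurkb (1.72, SE 0.54), Cst7 (1.78, SE 0.42), Il2rb (1.11, SE 0.33) and Slc4a1 (-0.46, SE 0.28). The knockout effect went with the level of the gene in both populations, as given above, and these list calls were not matched on level. Without the WT preproNK replicate 1 array 1309 genes were called. The interleukin receptor list lost its call without WT ALP replicate 1 or WT preproNK replicate 2 (adjusted p = 0.0768 and 0.118), the cytotoxic list without WT ALP replicate 1 or WT preproNK replicate 1 (0.0724 and 0.113) and the erythroid list without WT ALP replicate 1, WT preproNK replicate 1 or KO preproNK replicate 1 (0.0612, 0.0709 and 0.0786). Without the narrow-range array NK receptors (adjusted p = 0.0245) were called up, and innate lymphoid precursor (0.00794), mast cell (0.033) and clock genes (0.00491) down. NK receptors were also called up without KO ALP replicate 1, KO preproNK replicate 1 or WT ALP replicate 2 (adjusted p = 0.00858, 0.0316 and 0.00262), mast cell genes down without KO ALP replicate 2 or KO preproNK replicate 1 (0.0333 and 0.0073) and clock genes down without KO preproNK replicate 1 (0.0154). Immediate early genes were called up without KO ALP replicate 1 or WT ALP replicate 2 (adjusted p = 0.0139 and 0.0441), dendritic cell genes down without KO preproNK replicate 2 (0.00488) and early lymphoid progenitor genes down without WT ALP replicate 2 (0.0136).

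More genes were called between the populations than between the genotypes (391 against 0 in the means), which does not compare the sizes of the differences. Averaged over both genotypes, 11 of 20 early lymphoid progenitor genes fell from ALP to preproNK, and 12 of 15 T lineage and 9 of 15 innate lymphoid precursor genes rose. As lists they were called at the preset correlation and not with an estimated correlation (adjusted p = 0.052, 0.052 and 0.109). Dntt, which encodes terminal transferase, fell 64.2-fold (log2 difference -6.01, SE 0.27, adjusted p = 0.000286). Cd34, a surface protein of stem and progenitor cells, fell at least 16.9-fold (-5.25, SE 0.35), Sh2d5 at least 25.4-fold (-5.22, SE 0.30), Adgrg1, an adhesion receptor, 29.8-fold (-4.90, SE 0.26), Il12a at least 23.7-fold (-4.85, SE 0.57) and Flt3 at least 23.3-fold (-4.64, SE 0.35). The T cell receptor gamma gene Trgv1 rose at least 37.3-fold (5.98, SE 0.75), Cd3e at least 29.2-fold (5.72, SE 0.43), the transcription factor gene Ikzf3 41.1-fold (5.36, SE 0.73), Gimap3 37.8-fold (5.24, SE 0.49), Thy1 at least 30.7-fold (4.98, SE 0.35) and Cd3g at least 19.6-fold (4.86, SE 0.69). The adjusted p of these 12 genes was at most 0.0115. Folds given as at least a value count levels below an array's median as that median, and the log2 differences beside them are as fitted. The cells were sorted from Id2-GFP reporter mice. In this and the following comparisons of the populations, differences in Id2, or in any other gene used in the sort, may be set by the sort. They are then no independent result.

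Of the 15 tested T lineage genes 12 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 1.9e-19, 0.052 with an estimated correlation). Of 15 innate lymphoid precursor genes 9 rose (14 adjusted over the list alone; adjusted p = 1.16e-18, 0.109 with an estimated correlation), among them the costimulatory receptor gene Icos (3.99, SE 0.32) and Zbtb16 (2.56, SE 0.28). Of 16 NK transcription factors 5 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 1.64e-06, 0.117 with an estimated correlation), with Tbx21 at 4.19 (SE 0.31) and Id2 at 3.38 (SE 0.49). Of 14 interleukin receptor genes 5 rose (8 higher and 1 lower adjusted over the list alone; adjusted p = 1.64e-06, 0.243 with an estimated correlation), with Il2rb at 3.53 (SE 0.33) and Il18r1 at 3.32 (SE 0.41). Of 15 NK receptors 2 rose, Klrk1 (2.89, SE 0.34) and Klrc1 (2.57, SE 0.30), and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 2.07e-05, 0.109 with an estimated correlation). With the floor Tbx21 stood at 2.93, Klrk1 at 2.28 and Klrc1 at 1.24. Of 14 cytotoxic genes 1 rose, Ccl5 (3.32, SE 0.30), with 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.00137, 0.109 with an estimated correlation). Of 20 early lymphoid progenitor genes 11 fell and 0 rose (14 and 0 adjusted over the list alone; adjusted p = 5.42e-19, 0.052 with an estimated correlation). Of 28 cell cycle genes 2 fell, the replication helicase gene Mcm7 (-1.97, SE 0.34) and the spindle gene Tpx2 (-1.63, SE 0.34), and 13 were lower adjusted over the list alone (adjusted p = 4e-11, 0.232 with an estimated correlation). Of 12 clock genes 1 rose, the core clock factor Arntl (2.32, SE 0.32), with 6 higher adjusted over the list alone (adjusted p = 0.00132, 0.117 with an estimated correlation). With the floor Arntl stood at 1.697. Its other probe set, with a mean level of 3.686, differed by 0.476 in WT and 0.533 in KO. Lists of neutrophils and monocytes, dendritic cells, B cells, erythroid cells, mast cells, the BCL2 family, immediate early and heat shock genes and the interferon response were not called. The erythroid list had an adjusted p of 0.055, and one of 0.0311, upward, with the replicate number as a block. Without the narrow-range array the B lineage list was called down (adjusted p = 0.0477, 0.216 with all arrays). Dendritic cell genes were called down without KO preproNK replicate 2 (adjusted p = 5e-04, 0.132 with all arrays) and mast cell genes up (0.0312), and erythroid genes up without KO preproNK replicate 1 (0.00603).

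By limma 391 genes were called between the populations, 205 higher and 186 lower in preproNK, and all 391 had the same sign in both genotypes. Genes picked by the mean of both genotypes tend to have equal signs, and over all tested genes 7548 of 11583 did. With the replicate number as a block 852 were called, which included the 391. Leaving out WT ALP replicate 1 or 2 gave 119 and 221 calls, KO ALP replicate 1 or 2 gave 81 and 120, WT preproNK replicate 1 or the narrow-range replicate 2 gave 1058 and 869, and KO preproNK replicate 1 or 2 gave 35 and 69. Within the replicate 1 arrays alone 2566 genes were called and within the replicate 2 arrays alone 5, each with 4 arrays. Nfil3 itself differed by -0.76 (SE 0.37, adjusted p = 0.419).

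In WT, the comparison asked how the populations differ with Nfil3 present. Dntt fell 56.2-fold from ALP to preproNK (log2 difference -5.81, SE 0.38), Sh2d5 at least 21.6-fold (-5.17, SE 0.43), Cd34 at least 13.3-fold (-4.95, SE 0.49), Adgrg1 29.6-fold (-4.89, SE 0.37), Flt3 at least 20.7-fold (-4.49, SE 0.49) and Sox4, a transcription factor of progenitors, 11.8-fold (-3.56, SE 0.43). The 4 genes that rose were Stab2, a scavenger receptor (5.20, SE 0.50), Thy1 (4.09, SE 0.49), Icos (3.96, SE 0.45) and Camk4, a calcium-dependent kinase (3.48, SE 0.39). The adjusted p of these 10 genes was between 0.00519 and 0.0401. Not past the test stood 5830411N06Rik (3.12, SE 0.42, adjusted p with the block 0.0302), Tbx21 (2.83, SE 0.44, adjusted p = 0.0983, with the block 0.0348), Gata3 (2.85, SE 0.93), Id2 (2.64, SE 0.69), Zbtb16 (2.15, SE 0.40), Il2rb (1.99, SE 0.46), Ets1 (1.75, SE 0.91), Eomes (0.71, SE 0.56), Rag1 (-0.04, SE 0.46) and Nfil3 (-1.45, SE 0.52, adjusted p = 0.507). Tbx21 and Gata3 were below the median on both WT ALP arrays, and with the floor they stood at 1.499 and 2.08.

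Camera called 11 of 17 lists in WT, and 0 with an estimated correlation. Of 20 early lymphoid progenitor genes 4 fell (11 adjusted over the list alone; adjusted p = 1.36e-16, 0.106 with an estimated correlation). Of 15 innate lymphoid precursor genes 1 rose (10 adjusted over the list alone; adjusted p = 8.7e-18, 0.142 with an estimated correlation), and of 15 T lineage genes 1 rose (5 adjusted over the list alone; adjusted p = 2.15e-11, 0.142 with an estimated correlation). The other called lists had no member past the test over all genes. Cell cycle genes moved down (adjusted p = 5.92e-14, 0.202 with an estimated correlation), with Mcm7 at -2.50 (SE 0.48, adjusted p with the block 0.0378), and so did dendritic cell genes (adjusted p = 0.0344, 0.392 with an estimated correlation), with Irf8 at -2.97 (SE 0.52, adjusted p with the block 0.0466). Upward moved NK transcription factors (adjusted p = 3.55e-05, 0.187 with an estimated correlation), interleukin receptors (adjusted p = 0.00179, 0.392 with an estimated correlation) and NK receptors (adjusted p = 0.0329, 0.267 with an estimated correlation), in which Cd244a stood at -1.95 (SE 0.46). Clock genes (adjusted p = 0.000173, 0.142 with an estimated correlation), with Arntl at 1.86 (SE 0.46), erythroid genes (adjusted p = 0.00383, 0.158 with an estimated correlation), with Gata1 at 1.23 (SE 0.48), and mast cell and megakaryocyte genes (adjusted p = 0.0344, 0.267 with an estimated correlation), with Mcpt8 at 2.05 (SE 1.12), were also up. With the floor Arntl stood at 1.475 and Gata1 at 0.812. With the replicate number as a block the NK receptor and dendritic cell lists were not called (adjusted p = 0.0521 and 0.118). Without WT ALP replicate 1, WT ALP replicate 2 or WT preproNK replicate 1 these lists lost their call too (NK receptors, adjusted p = 0.0894, 0.0657 and 0.416; dendritic cell, 0.0611, 0.0657 and 0.439), and without the last so did interleukin receptors (0.453). Erythroid genes lost theirs without the narrow-range array (adjusted p = 0.0735), and mast cell and megakaryocyte genes without that array, WT ALP replicate 1 or WT preproNK replicate 1 (0.371, 0.335 and 0.0911). Without the narrow-range array B lineage genes were called down (adjusted p = 0.0404) and immediate early genes up (0.0331). Repeated quantile normalization ended the calls of NK receptors (adjusted p = 0.0886), dendritic cell (0.0594) and mast cell genes (0.073). By limma 11 genes were called, 4 higher and 7 lower in preproNK, against 41 higher and 29 lower after repeated quantile normalization and 67 with the block. Without the narrow-range WT preproNK replicate 2 array there were 164, without WT preproNK replicate 1 824, without WT ALP replicate 1 or 2 0 and 4, without either KO ALP array 3 and without either KO preproNK array 2.

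In KO, the comparison asked how the populations differ without Nfil3. Trgv1 rose at least 73-fold from ALP to preproNK (log2 difference 7.15, SE 1.06), Cd3e at least 76.1-fold (7.12, SE 0.61), Cd3g at least 71.3-fold (6.70, SE 0.97), 5830411N06Rik at least 82.7-fold (6.56, SE 0.42), Ikzf3 92.1-fold (6.53, SE 1.04) and Ccr6, a chemokine receptor, at least 45.3-fold (6.05, SE 0.67). Dntt fell 73.4-fold (-6.20, SE 0.38), Cd34 at least 21.5-fold (-5.54, SE 0.49), Il12a at least 37-fold (-5.51, SE 0.81), Sh2d5 at least 29.8-fold (-5.27, SE 0.43), Adgrg1 30.1-fold (-4.91, SE 0.37) and Bcl11a, a transcription factor of progenitors, 29.2-fold (-4.87, SE 0.56). The adjusted p of these 12 genes was between 0.00221 and 0.0279. Of the followed genes Tbx21 (5.55, SE 0.44, or 4.356 with the floor), Il2rb (5.06, SE 0.46), Id2 (4.12, SE 0.69) and Zbtb16 (2.97, SE 0.40) rose and Flt3 fell (-4.79, SE 0.49). Gata3 (2.66, SE 0.93), Ets1 (2.46, SE 0.91), Eomes (0.45, SE 0.56), Rag1 (-0.96, SE 0.46) and Nfil3 (-0.07, SE 0.52) did not pass the test, with adjusted p from 0.31 to 1.

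Of 15 T lineage genes 12 rose in KO (13 adjusted over the list alone; camera adjusted p = 2.43e-25, 0.0319 with an estimated correlation), among them Thy1 (5.86, SE 0.49). Of 20 early lymphoid progenitor genes 9 fell (13 adjusted over the list alone; adjusted p = 1.08e-21, 0.0319 with an estimated correlation). These 2 of the 9 called lists held with an estimated correlation. Of 15 innate lymphoid precursor genes 6 rose (13 adjusted over the list alone; adjusted p = 7.1e-18, 0.107 with an estimated correlation), among them Icos (4.01, SE 0.45). Of 16 NK transcription factors 4 rose (6 higher and 1 lower adjusted over the list alone; adjusted p = 2.51e-07, 0.107 with an estimated correlation). Of 14 interleukin receptors 2 rose (7 adjusted over the list alone; adjusted p = 8.8e-09, 0.225 with an estimated correlation), Il2rb and Il18r1 (4.65, SE 0.58). Of 15 NK receptors Klrc1 (4.26, SE 0.42) and Klrk1 (4.19, SE 0.47) rose (7 higher and 1 lower adjusted over the list alone; adjusted p = 2.51e-07, 0.0725 with an estimated correlation). With the floor Klrc1 stood at 2.90 and Klrk1 at 3.55. Of 14 cytotoxic genes Ccl5 (4.38, SE 0.42) and Gzmb (2.07, SE 0.37) rose (5 adjusted over the list alone; adjusted p = 3.7e-05, 0.0582 with an estimated correlation). Arntl rose (2.78, SE 0.46, or 1.919 with the floor) among 12 clock genes (2 adjusted over the list alone; adjusted p = 0.0303, 0.225 with an estimated correlation). The cell cycle list moved down (adjusted p = 1.16e-05, 0.38 with an estimated correlation) with 0 of 28 members past either gene test and Tpx2 at -1.61 (SE 0.48), and its median was -1.56 within replicate 1 and 0.0871 within replicate 2, with 12 of 28 members lower in both. Without KO preproNK replicate 1 the cell cycle and clock lists lost their call (adjusted p = 0.141 each), as did the clock list without KO ALP replicate 1 (adjusted p = 0.112). Dendritic cell genes were called down without KO preproNK replicate 2 (adjusted p = 0.000367, 0.334 with all arrays) and B lineage genes down without that array or KO ALP replicate 1 (0.0485 and 0.0444). By limma 203 genes were called in KO, 141 higher and 62 lower in preproNK, against 449 with the block and 1234 from the 4 KO arrays alone. Leaving out KO ALP replicate 1, KO ALP replicate 2, KO preproNK replicate 1 or KO preproNK replicate 2 left 0, 2, 0 and 0 calls, and leaving out either WT preproNK array 530.

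The population differences in WT and in KO, which share no array, correlated with r = 0.66 across genes, which are not independent replicates. That correlation was 0.831 within the replicate 1 arrays and 0.19 within the replicate 2 arrays. The slope of KO on WT by total least squares was 1.22, and 1.19 and 0.701 within the numbers. All 11 genes called in WT were among the 203 called in KO with the same direction, where independent lists would share 0.0862. Both sets of calls use the same estimate of each gene's spread, so they are not independent, and 0.0862 is too low a reference. The larger number of calls in KO does not show a larger difference, since no gene was called in the test of the interaction. The knockout effects in ALP and in preproNK, which also share no array, correlated with r = 0.56. Within the replicate 1 arrays the value was 0.14 and within the replicate 2 arrays 0.56, and it was -0.19 without the WT ALP replicate 2 array, 0.0735 without KO ALP replicate 1 and 0.136 without the WT preproNK replicate 2 array.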

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

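The tests of probe set agreement, of hybridization controls and of other splits for the population difference were set before their own values were seen, and the other tests of explanations in this part were chosen after the results were seen. The tests of the interaction by gene list picked out 8 lists in which the knockout effect differed between ALP and preproNK. Their camera adjusted p was 5.81e-20 for T lineage, 9.81e-06 for interleukin receptors, 9.81e-06 for NK receptors, 4.89e-05 for cytotoxic effectors, 0.000648 for cell cycle, 0.000938 for early lymphoid progenitor genes, 0.00417 for NK transcription factors and 0.0136 for erythroid genes. With an estimated correlation none of the 8 was past 0.05, and the lists were not matched on level. Among probe sets with no gene name, 208 of 7820 tested were called between the populations, 118 higher and 90 lower in preproNK, and nothing is said of them in the comparisons above.

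The T lineage list was called up in KO against WT preproNK by camera at its preset correlation but not with an estimated correlation (adjusted p = 0.176), with 0 of 15 members called over all genes and Cd8a and Cd8b1 lower in the replicate 2 pair (-0.854 and -0.676). The narrow-range WT preproNK replicate 2 array as the only source is argued against by the replicate 1 pair, which does not hold it and in which the list's median was 1.56. That median lay at percentile 100 of 10000 lists of the same size matched on mean level. Those lists were drawn gene by gene, so the percentile does not allow for genes that move together. The dendritic cell, erythroid and early lymphoid progenitor lists lay at percentile 0 in the same pair. A lower share of the main cell type stays open. It would raise markers only of types present in the samples, which bulk values do not give. The T lineage median exceeded the highest median among the B lineage, neutrophil, dendritic cell, erythroid and mast cell lists by 1.61 in the replicate 1 pair. The SE of that difference, 0.403, treats genes as independent. In the replicate 2 pair the dendritic cell list also had a high median (1.32 against 1.93). The B lineage, erythroid and mast cell medians there were -0.523, -0.406 and -0.619. These values argue only against an equal rise of the markers of all these types. A higher share of T-like cells in the KO samples stays open, as 13 of 15 members were higher in both pairs, and cannot be told apart from a higher level per cell, since expression of sorted bulk cells does not give shares. Depletion of lineage cells would remove cells with surface CD3 only if the antibody mix held it, which the labels do not say.

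The WT preproNK replicate 2 array stood apart, and no biological explanation of this was tested. A mislabelled sample of ALP alone is argued against by the 203 genes called between the KO populations, over which its place between the KO means correlated with the KO population difference at 0.402 (0.762 for WT preproNK replicate 1, -0.986 and -0.939 for the WT ALP arrays) and 93 genes lay nearer KO preproNK (153 for WT preproNK replicate 1, 0 and 2 for the WT ALP arrays). Most of the 203 lay nearer KO ALP, and its highest correlations were with 2 ALP arrays (0.747 and 0.656). Its correlations with all arrays (0.504 to 0.747) were below those between ALP and preproNK arrays among the other 7 (0.756 to 0.876). These values argue against a well measured sample of both populations as the only explanation. Such a mixture together with a noisy measurement was not excluded. A fault in hybridization or scanning stays open. The slope of 18 bacterial control probe sets on their mean over the other arrays was 0.876. It lay within the range of the others (0.75 to 1.13), as the bound set beforehand against a fault required. That held only through WT ALP replicate 2, the other narrow-range array, while the remaining 6 lay from 0.955 to 1.13. The control means were higher on these 2 narrow-range arrays (9.96 and 10.3) than on the remaining 6 (8.29 to 9.45). They are therefore no sign of weak hybridization of the controls. A noisy measurement of this sample, from a source not known, is a candidate explanation, as residuals of pairs of probe sets of 4195 genes correlated at 0.32 on this array, below the 0.404 to 0.746 of the other 7.

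The 391 calls between populations were set against other splits of the 8 arrays. In a fit of 2 groups, the real split gave 445 calls and the highest of the other splits 0. So 1 of 35 splits gave as many, the smallest share this test can give. That share is under 0.05 only in a comparison that leaves the pairing by replicate number out. The other splits put arrays of both populations in each group, which widens the spread within it. Few calls were therefore likely there in advance, and the test does not exclude chance. The 18 splits that divide the replicate numbers equally, the fitting comparison for paired numbers, are too few for a share under 0.05, and there the real split gave 445 and the highest other 0. For the knockout effect averaged over both populations the real split gave 0 calls, which all 35 of 35 splits must reach, so this count says nothing of chance. The highest other split there, that of the populations, gave 445, a structure of the samples.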

How the results depend on the processing

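The array weights and the blocked fit without the WT preproNK replicate 2 array were chosen after seeing the data. The fits that leave out an array assume that a lone sample varies like the other groups. Of the 59 called values of named genes 0 changed direction in any setting, and of 94 values not called 8 did. With the replicate number as a block 59 of the 59 kept their call and 9 of the 94 became called. Beyond the genes and lists given with their blocked values above, the block changed no other call of a named gene or list. Without KO preproNK replicate 1 45 of the 59 lost their call and without the WT preproNK replicate 2 array 0 did. In ALP, for the interaction, and for the knockout averaged over both populations, no alternative called a gene, except 1309 without WT preproNK replicate 1 in the last. The cause of the changes below was not tested, except that leaving out arrays or using 4 of them changes the spread the fit estimates.

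For KO against WT in preproNK (0 calls) the block gave 10, array weights 35, gene by gene weights 165, and the block without the narrow-range array 47; leaving out an array gave 0 to 2532. For the populations in WT (11) the block gave 67, no filter 6, repeated quantile normalization 70, centring 20, array weights 292, gene by gene weights 494, the block without the narrow-range array 431 and the 4 arrays alone 0; leaving out an array gave 0 to 824. In KO (203) the block gave 449, array weights 1033, gene by gene weights 966, the block without the narrow-range array 1238 and the 4 arrays alone 1234; leaving out an array gave 0 to 530. For the mean of both genotypes (391) the block gave 852, array weights 1313, gene by gene weights 1595, the block without the narrow-range array 1661, replicate 1 alone 2566 and replicate 2 alone 5; leaving out an array gave 35 to 1058. For the knockout averaged over both populations leaving out an array gave 0 to 1309.

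The number of lists called with an estimated correlation was 0 in 6 comparisons and 2 for the populations in KO. By fry it was 0 for KO against WT in ALP and for the interaction, 2 for KO against WT in preproNK and 2 for the populations in WT. It was 8 for the populations in KO, 10 for the mean of both genotypes and 1 for the knockout averaged over both populations. Lists called by fry and not by camera were the B lineage, down, in KO (adjusted p = 0.0313) and in the mean of both genotypes (0.015). In that mean fry also called the BCL2 family up (adjusted p = 0.0288). In ALP (2 lists) the block and repeated quantile normalization gave 0, the block without the narrow-range array 1 and leaving out an array 0 to 2. No filter gave 8 for the knockout averaged over both populations (5), and leaving out an array 2 to 8. Leaving out an array gave 7 to 11 lists for the populations in WT (11) and 5 to 11 for the interaction (8). The adjusted p of the cell cycle list in ALP was 0.000766 to 0.645 when an array was left out, with the direction turned at the highest.

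Of the values that turned, Eomes in KO against WT preproNK was 0.0257 with the mean of its probe sets, 0.21 and 0.30 with the 2 array weights, 0.22 with the block without the narrow-range array, 0.51 on its probe set number 2 by mean level, and -1.31 to 0.38 when an array was left out. Ets1 was -0.032 with gene by gene weights, -0.25 on its probe set number 3 and -0.15 to 2.75 when an array was left out. Flt3 was 0.0858 with quantile normalization, 0.18 and 0.25 with the weights, 0.49 with the block without the narrow-range array and -0.36 to 0.32 when an array was left out. Id2 was -0.21 and -0.36 with the weights, -0.39 with the block without the narrow-range array and -0.51 to 1.80 when an array was left out, and Gata3 -1.82 to 1.5. Between the populations in WT, Rag1 was 0.0182 after centring and -0.60 to 0.53, and Eomes -0.13 to 1.56, when an array was left out. Between those in KO, Nfil3 was -0.44 to 0.29. The correlation of the knockout effects (0.56) was 0.0973 from opposite replicate numbers and -0.19 to 0.62 when an array was left out, and the slope of the population differences (1.22) 0.406 to 1.45. Lists not called became called, with their direction kept, 41 times over the comparisons when an array was left out, 9 times without a filter, 5 times with the mean of probe sets and 2 times after quantile normalization, and 3 times with the direction turned when an array was left out. Fry added 3 such calls and the block 2, all with the direction kept. The block without the narrow-range array, which leaves 1 WT preproNK sample, also added calls, some with the direction turned. The clock list in KO (adjusted p = 0.0303) had 0.0639 with the mean of probe sets, and the erythroid list 0.0516 without a filter for the interaction and 0.0579 after quantile normalization for the mean knockout effect.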

Other observations

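Both gene lists of this paragraph were assembled after the values were seen. In preproNK the genes that differed between genotypes in the replicate 1 pair included markers of 2 kinds of lymphocyte, in opposite directions. A list of 12 tested genes of gamma delta T cells, of which Blk, Ccr6 and Zbtb16 are also in the fixed lists, had a median log2 difference between KO and WT of 2.11 in the replicate 1 pair and 2.91 in the replicate 2 pair, and 11 of 12 were higher in KO in both. In the replicate 1 pair Sox13 differed by 3.28, 5830411N06Rik by 3.04, Ccr6 by 2.53, Cd163l1 by 2.37, Blk by 2.19 and Il17re by 2.18. Trgv1 differed by -0.10 there and by 3.64 in the replicate 2 pair. A list of 10 tested genes of group 2 innate lymphoid cells had a median of -2.10 in the replicate 1 pair, with Arg1 at -3.73, Pparg at -2.93, Rxrg at -2.33, Ccr9 at -2.32, Stab2 at -2.29, Il17rb at -1.91 and Gata3 at -1.52. In the replicate 2 pair, which holds the narrow-range array, its median was 0.07, with Arg1 at -0.87, Pparg at -1.79 and Gata3 at 1.20, and 4 of 10 members were lower in KO in both pairs. The fixed list of innate lymphoid precursor and ILC2 or ILC3 genes, which shares Arg1, Gata3, Icos and Il17rb with it, had medians of 0.131 and 1.2 in the replicate 1 and replicate 2 pairs and was called down without the narrow-range array (camera adjusted p = 0.0137). These lists were assembled from genes seen to differ, so their medians show the pattern and do not test it.

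Genes linked to sex and date coincided on 7 of the 8 arrays. All 4 replicate 1 arrays had Xist values from 3.10 to 3.56 and values of the Y-linked Eif2s3y from 6.60 to 7.04. The replicate 2 arrays of WT ALP, KO ALP and KO preproNK had Xist at 7.94, 9.30 and 8.78 and Eif2s3y at 5.22, 4.61 and 5.07. The WT preproNK replicate 2 array had Xist at 4.2 and Eif2s3y at 4.19. Both lay below its median over all probe sets (4.265), so it showed clear signal of neither gene. The mean of the 18 hybridization controls was 10.3 on WT ALP replicate 2 and 9.96 on WT preproNK replicate 2, the arrays with the narrowest ranges, against 8.29 to 9.45 on the other 6. The 3' minus 5' difference of the Actb control probe sets was -0.73 on WT preproNK replicate 2, within the -0.96 to -0.35 of the other 7.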
